A study of Mus musculus with 6 samples.

How the data were processed

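Brown adipose tissue, the heat-producing fat depot of small mammals, was taken from male C57BL/6J mice that had been injected intraperitoneally for 2 weeks with phosphate-buffered saline (PBS) or with ginsenoside Rb2. Ginsenosides are steroid-like saponins of ginseng root. Per the labels' protocols, RNA of 3 mice per group was extracted with a silica-column kit and turned into strand-marking, poly(A)-selected libraries.

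The values used are the read counts per gene that the authors deposited in 1 table of 45777 genes and 6 libraries. They are whole numbers, not normalized, and differ in their totals between libraries. Per the submitters' processing notes, Trimmomatic, HISAT2, Bowtie2 and StringTie were used with the mm10 mouse genome. Their roles, versions and settings, the program that counted the reads, and whether it used strand are not given in the sources used here. The table's columns carry the group and a number: 1, 2 and 4 for PBS and 1, 3 and 4 for Rb2. These numbers cannot be tied to the replicate numbers of the sample titles, so the libraries are named by the column numbers, and the numbers pair nothing. Genes are given by the symbol and NCBI gene ID of the table, and positions come from the RefSeq annotation of GRCm38, the assembly that mm10 stands for.

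Total counts ran from 83642183 (PBS 1) to 92666780 (PBS 4), so a count of 0 allows at most 3 counts, or 0.0359 CPM (the count scaled to a common library size) in the smallest library. This floor covers counting error only. No pair of libraries was a duplicate: Pearson r of log2 CPM across genes ran from 0.920 to 0.979. PBS 4 had a higher r with Rb2 1, 3 and 4 (0.969, 0.965 and 0.972) than with PBS 1 (0.959) and PBS 2 (0.948).

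Genes were tested with the quasi-likelihood F test of edgeR (version 4.0.16, R 4.3.3) on the counts as deposited, with TMM normalization, robust dispersions and the default expression filter (a count minimum of 10 in enough libraries and a total of at least 15). The filter left 16707 genes. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. A standard error (SE) is the log2 fold change divided by the square root of F. Expression levels are TMM-normalized CPM, given as mean ± SD of 3 libraries. With 3 libraries against 3, chance alone separates the groups completely in 10% of genes.

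Before the data were examined, 44 gene lists for brown fat function, metabolism, stress responses and the other cell types of the depot were fixed, as were the test, the alternatives and the rule for named genes. Of the list entries, 957 were matched by symbol, 6 by a RefSeq synonym and 13 mitochondrial genes by position on the mitochondrial genome, with an overlap of at least 95%. Lists with at least 5 tested members were tested with limma's camera (version 3.58.1) on voom log2 CPM with a preset correlation of 0.01 between genes. A camera call compares the members with all other tested genes. Each list count is also given "adjusted over the list alone", with the Benjamini-Hochberg method applied within the list.

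The rule names the 10 largest rises and the 10 largest falls among genes past the threshold with a mean of at least 1 CPM in the higher group and no overlap between groups. It always names Ucp1, Ppargc1a, Dio2, Cidea, Elovl3 and Prdm16. From a list that passed camera or had at least 3 members past the threshold it takes up to 4 members with the smallest p, and from any other list up to 2. Members named beyond the rule are said to be so.

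The alternatives planned before the data were examined were DESeq2's size factors, upper-quartile factors, library size alone, the DESeq2 Wald test (version 1.42.0), limma-voom, no filter, a count minimum of 50, an adjusted p under 0.1, an added 2-fold minimum, and each library left out in turn. For the lists they were an estimated correlation and the directional and mixed tests of limma's fry. A block on the title's replicate numbers was planned and could not be run. The alternatives chosen after seeing the data were a block on the column numbers that both groups carry, the mean log2 CPM of the skeletal muscle list as a covariate, an offset for GC content and transcript length, and leaving out both PBS libraries with the most muscle transcripts. The offset came from a natural spline with 5 degrees of freedom each for the GC content and log length of a gene's longest GENCODE transcript, fitted per library, and 94.4% of tested genes had these values.

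The tests were tried on simulated counts drawn with the real means, library sizes and dispersions for 16707 genes in the Rb2 against PBS design. Of 100 genes changed 2-fold, 40 were called in the right direction, and of 100 changed 4-fold, 71 were. In all 124 genes were called, 13 of them unchanged ones, which is a larger share than the nominal 0.05. Far fewer genes were changed in the simulation than the 1743 called in the data, and the adjusted threshold depends on that number. The recovered shares therefore do not measure the power of the real comparison. In the same design, camera called the 1 list of 43 that was shifted 1.5-fold and none of the lists that shared no gene with it; these simulated genes were independent of each other.

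Among the 167 genes that the rule names, 58 overlap another gene of the table on the genome. As the use of strand in counting is not given, their counts may hold reads of the other gene, as may those of near-identical copies such as the haemoglobin genes.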

Results

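Messenger RNA was measured in brown adipose tissue of male C57BL/6J mice treated for 2 weeks with PBS or with ginsenoside Rb2, 3 mice per group. The deposited counts held 45777 genes, of which 24703 had a count in at least 1 library and 16707 entered the test. Total counts were 83642183, 90796497 and 92666780 in PBS 1, 2 and 4, and 89924631, 87545902 and 89688383 in Rb2 1, 3 and 4. Expression is given as the mean ± SD of TMM-normalised expression (CPM, the count scaled to a common library size) over the 3 mice of a group. Transcripts encoded by the mitochondrial genome took 35.8% to 42.4% of the counts. The single comparison of the design asks what Rb2 changed in this tissue.

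Brown fat of Rb2-treated mice differed from that of PBS-treated mice in 1743 genes, of which 890 were higher and 853 lower after Rb2 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). With library size alone as scaling 38.7% of the called genes were higher (492 higher, 779 lower), against 51.1% with TMM factors. Changes of at least 2-fold made up 242 of the higher and 322 of the lower genes. The largest rise was that of Dbp, a clock-controlled transcription factor (gene 13170; chromosome 7, 45705100 to 45710203 in GRCm38.p6). It went from 6.69 ± 1.63 to 95.5 ± 35.6 CPM (log2 fold change 3.84 ± 0.36 SE, adjusted p = 0.00537). Other large rises were those of Fgf16, a fibroblast growth factor (log2 fold change 2.70, adjusted p = 0.0158), Il1rn, the interleukin-1 receptor antagonist (2.59, adjusted p = 0.00695), and Btc, a ligand of the EGF receptor (2.43, adjusted p = 0.0408). The largest fall was that of Ankrd37 (gene 654824; chromosome 8, 45996908 to 46000414), from 2.64 ± 0.19 to 0.210 ± 0.0471 CPM (log2 fold change -3.64 ± 0.29 SE, adjusted p = 0.00137). Fosb, a subunit of the AP-1 transcription factor (-3.38), Vdr, the vitamin D receptor (-3.17), Cyp1a1, a xenobiotic-metabolizing cytochrome P450 (-2.87), and Depp1 (-2.70) fell with adjusted p between 0.00258 and 0.00984.

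The remaining large rises were those of D330041H03Rik (3.06), Ciart (2.92), Rgs9bp (2.92), Gdap10 (2.87), Bhlhe41 (2.64) and Per3 (2.41). The remaining large falls were those of Hspa1l (-3.37), Kcng4 (-3.25), Tmem252 (-2.93), Mafa (-2.63) and Gprc5a (-2.53). All of the 1743 called genes were separated between the groups without overlap, which follows largely from their selection by the test. Of all tested genes 35.8% were separated, where chance gives 10% for a gene. Genes vary together over the libraries, so the 35.8% does not measure an excess over chance. Genomic overlap leaves the source of some of these counts open: Gdap10 lies within the region of Nampt, a far more abundant gene that itself rose, D330041H03Rik overlaps Abca3, Tmem252 overlaps Pgm5, and Dbp overlaps Sphk2 by 741 bases. Hspa1l has close relatives in the Hsp70 family.

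The number of called genes changed when 1 library was left out. Such a fit also has less power, so a lost call does not by itself mean that the change rested on that library. The number was 334 without PBS 1, 303 without PBS 2, 548 without Rb2 1 and 601 without Rb2 3. It was 1564 without PBS 4 and 2269 without Rb2 4. Whichever of the 6 libraries was left out, 219 genes (81 higher, 138 lower) were called. Of the 20 largest changes, 12 stayed past the threshold in all 6 of these tests. Those that did not were D330041H03Rik, Ciart, Rgs9bp, Gdap10, Fgf16, Btc, Kcng4 and Mafa, with 12 of the 20 kept without PBS 1, 13 without PBS 2, 16 without Rb2 1 and 16 without Rb2 3. With an offset for GC content and length D330041H03Rik (adjusted p = 0.0562), Btc (adjusted p = 0.0507), Kcng4 (adjusted p = 0.0616) and Mafa (adjusted p = 0.0628) no longer passed. Kcng4 (adjusted p = 0.108) and Mafa (adjusted p = 0.107) did not pass with the muscle markers as a covariate either.

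The main axis of variation between libraries (first principal component of log2 CPM, 51.8% of the variance) did not separate the groups. PBS 1, 2 and 4 were at -55.7, -77.5 and 25.0 on it, and Rb2 1, 3 and 4 at 78.7, 12.6 and 16.9. The libraries also differed in their muscle transcripts and in a trend with GC content. Skeletal muscle markers took 0.310%, 1.03% and 0.0155% of the counts in PBS 1, 2 and 4, and 0.0112%, 0.0675% and 0.0503% in Rb2 1, 3 and 4. Genes rich in G and C were relatively higher in PBS 2 and PBS 4 (Spearman rho across genes of a gene's deviation from its mean and its GC content 0.349 and 0.388; 0.00406 in PBS 1) and lower in Rb2 1, 3 and 4 (rho -0.289, -0.254 and -0.134). Across genes, which are not independent replicates, the log2 fold change and the GC content had a rho of -0.333. In the tenth of genes with the lowest GC content 199 were higher and 7 lower after Rb2, and in that with the highest GC content 21 were higher and 198 lower. With the muscle markers as a covariate 893 genes were called, 844 of them among the 1743. The covariate also uses up a degree of freedom, which lowers power. With an offset for GC content and length 1325 were called, 1034 of them among the 1743. No gene passed the threshold in edgeR with PBS 1 and PBS 2 left out, a test that leaves 1 PBS library and assumes that it varies like the Rb2 libraries. There 2063 genes had an unadjusted p under 0.05.

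**Figure D1:**
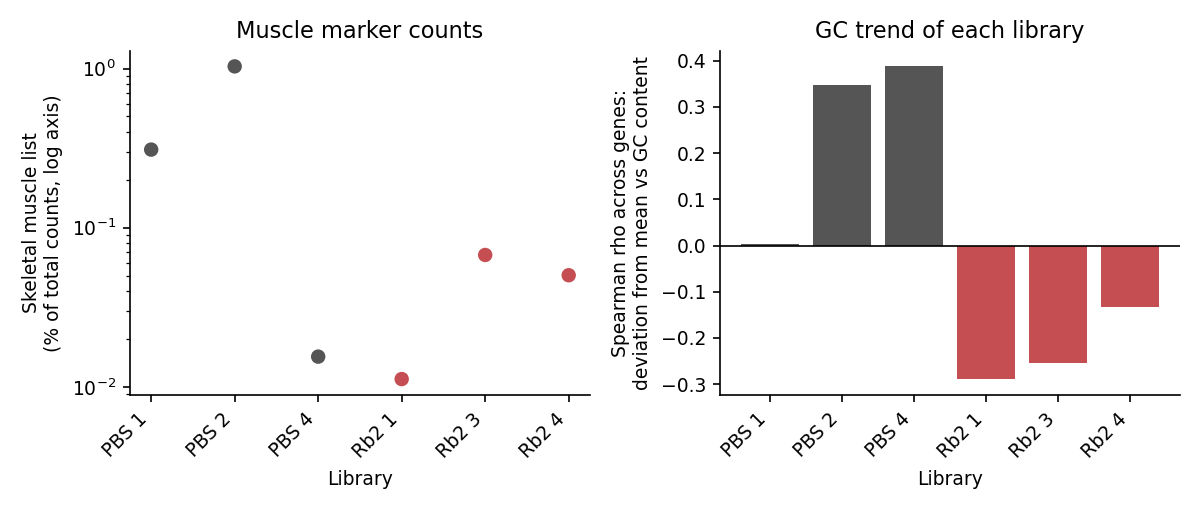
Left, the share of each library's total counts taken by the skeletal muscle list, in percent on a log axis; right, for each library, Spearman's rho across genes between a gene's log2 deviation from its mean and its GC content. Grey stands for PBS and red for Rb2, with 1 point or bar per library; the muscle share reaches 1.03% in PBS 2, and rho is negative in the 3 Rb2 libraries.

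Of the lists, that of the circadian clock had the largest share of members past the threshold: 10 of 19 rose and 4 fell. The counts adjusted over the list alone were also 10 and 4. Per3, a repressor of the core loop, rose from 5.19 ± 0.42 to 27.5 ± 2.53 CPM (log2 fold change 2.41 ± 0.14 SE, adjusted p = 0.000211). Tef, a relative of Dbp, rose from 40.6 ± 1.10 to 146 ± 14.5 CPM (1.84 ± 0.13 SE, adjusted p = 0.000864), and Cry2, another core repressor, from 10.9 ± 0.80 to 27.9 ± 2.17 CPM (1.36 ± 0.13 SE, adjusted p = 0.00214). Ciart (2.92 ± 0.54 SE) and Bhlhe41 (2.64 ± 0.31 SE), both transcriptional repressors tied to the clock, rose with Dbp. Nfil3, a repressor of the genes that Dbp activates, fell from 24.8 ± 5.47 to 6.84 ± 0.72 CPM (-1.86 ± 0.18 SE, adjusted p = 0.00252), and Per1 fell as well (-1.15 ± 0.22 SE, adjusted p = 0.0188).

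Further clock members, outside the rule for named genes and picked after their values were seen, were Hlf (2.23), Nr1d2 (1.66), Nr1d1 (1.40) and Per2 (1.22), which rose, and the activators Arntl (-1.75) and Npas2 (-2.03), which fell. Clock (0.06), Cry1 (0.03), Rora (0.14) and Bhlhe40 (1.09, adjusted p = 0.228) did not pass the threshold. The list passed camera (median log2 fold change 1.22, adjusted p = 0.000679), with adjusted p = 0.594 with an estimated correlation. Of its 14 calls 11 stayed whichever library was left out; Ciart, Per1 and Per2 did not, and 11 calls stayed without PBS 1, 12 without PBS 2 and 13 without Rb2 3. With the GC and length offset 13 stayed, all but Per1 (-0.89, adjusted p = 0.0545), and with the muscle covariate 14.

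**Figure D2:**
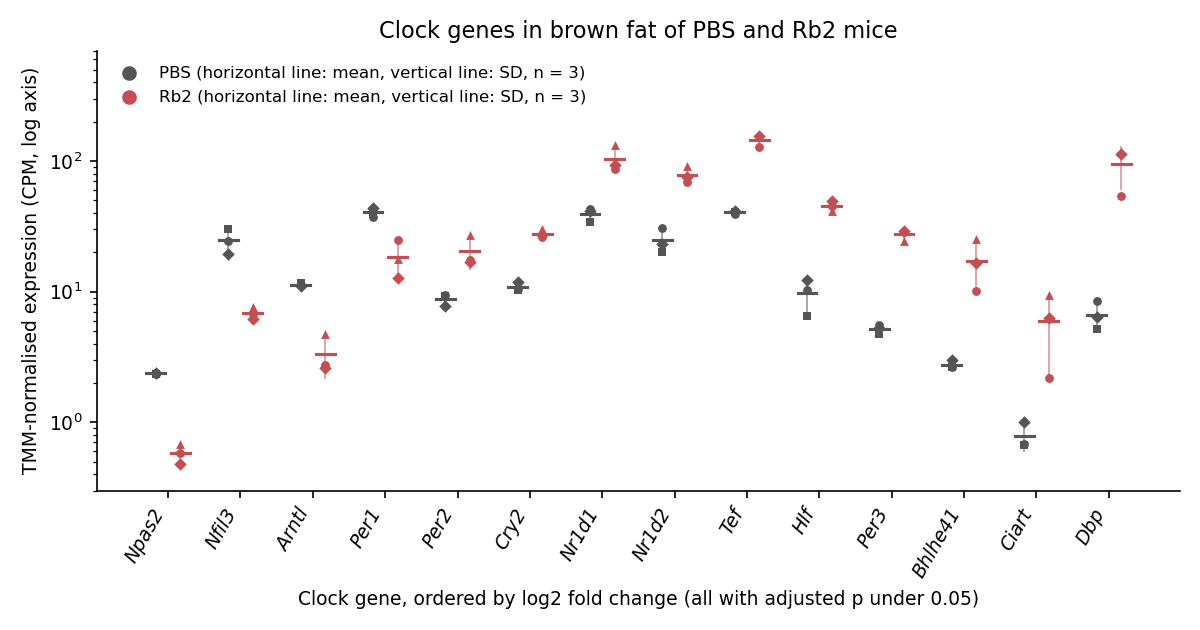
TMM-normalised expression of the 14 clock genes past the threshold in CPM on a log axis, ordered by log2 fold change, with 1 point per library (3 PBS, 3 Rb2), a horizontal line at each group's mean and a vertical line for its SD. The 10 genes that rose and the 4 that fell show no overlap between the groups, from Npas2 at -2.03 to Dbp at 3.84.

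Among genes of brown adipocyte identity and heat production the changes went both ways. Ucp1, the uncoupling protein that makes brown fat produce heat (chromosome 8, 83290348 to 83298456), was at 3983 ± 711 CPM with PBS and 3674 ± 910 CPM with Rb2 (log2 fold change -0.12 ± 0.21 SE, adjusted p = 0.749), a difference smaller than the spread between libraries. Ppargc1a, a coactivator of mitochondrial genes (0.03 ± 0.22 SE, adjusted p = 0.932), and Cidea, a lipid droplet protein (0.16 ± 0.18 SE, adjusted p = 0.581), did not pass the threshold either. Dio2, which activates thyroid hormone, had no overlap between the groups and did not pass (-1.38 ± 0.49 SE, adjusted p = 0.133). It passed without Rb2 3 (-1.89, adjusted p = 0.0470), in the DESeq2 Wald test (adjusted p = 0.0478) and with the muscle covariate (-0.99, adjusted p = 0.0446). Elovl3, a fatty acid elongase of brown fat, fell from 73.8 ± 19.0 to 22.0 ± 7.86 CPM (-1.74 ± 0.31 SE, adjusted p = 0.0214), and Prdm16, a transcriptional regulator of brown fat identity, from 26.9 ± 3.21 to 12.3 ± 1.88 CPM (-1.13 ± 0.15 SE, adjusted p = 0.00584). Pank1, an enzyme of coenzyme A synthesis (1.15 ± 0.18 SE, adjusted p = 0.0095), Adrb1, the beta-1 adrenergic receptor (1.58 ± 0.26 SE, adjusted p = 0.0129), and Gk, glycerol kinase (1.09 ± 0.20 SE, adjusted p = 0.0149), rose.

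Of the 29 members tested, 8 rose and 3 fell (10 and 4 adjusted over the list alone), and the list did not pass camera (adjusted p = 0.139; adjusted p = 0.594 with an estimated correlation). It did pass, upward, with the GC and length offset (adjusted p = 0.0383). Of these 11 calls 1 stayed without PBS 1, 2 without PBS 2, 7 without PBS 4, 6 without Rb2 1 and 6 without Rb2 3. Prdm16 kept its call in all 6 tests, while the adjusted p of Elovl3 reached 0.0851 without PBS 2. Prdm16 overlaps 5930403L14Rik by 5677 bases. Nuclear genes of oxidative phosphorylation did not shift as a list (2 higher, 2 lower of 55, none adjusted over the list alone; camera adjusted p = 0.508). Ndufs1 (0.83) and Uqcrc2 (0.63) rose and Ndufa2 (-0.84) and Atp5k (-0.72) fell, and none of these 4 calls stayed without PBS 1, PBS 2, Rb2 1 or Rb2 3, while 2 stayed without PBS 4. None stayed with the offset or with the muscle covariate. None of the 13 genes of the mitochondrial genome passed edgeR's threshold (camera adjusted p = 0.253, and 0.0312, upward, without PBS 1). ATP8 had a log2 fold change of 0.62 (adjusted p = 0.0928) and ND4 of 0.40 (adjusted p = 0.191).

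Enzymes that break down branched-chain amino acids, fatty acids and acetyl-CoA in mitochondria were higher after Rb2 by camera with the preset correlation. None of these 3 lists passed with an estimated correlation (adjusted p = 0.594 for each). In branched-chain amino acid catabolism 8 of 19 members rose and none fell (14 adjusted over the list alone; median log2 fold change 0.50, camera adjusted p = 1.32e-07). Ppm1k, the phosphatase that activates the branched-chain ketoacid dehydrogenase, rose from 12.1 ± 1.50 to 27.3 ± 2.78 CPM (1.18 ± 0.14 SE, adjusted p = 0.00406), and Dbt (0.88), a subunit of that complex, Hibch (0.78) and Mmut (0.88) rose with it. In the TCA cycle 7 of 18 members rose (13 adjusted over the list alone; median 0.60, camera adjusted p = 4.18e-06), among them Idh3a from 850 ± 147 to 1485 ± 174 CPM (0.80 ± 0.18 SE, adjusted p = 0.0243), Dld (0.77), Sucla2 (0.65) and Suclg2 (0.61). In mitochondrial fatty acid oxidation 5 of 20 rose (9 adjusted over the list alone; median 0.39, camera adjusted p = 1.01e-05), led by Etfdh (0.83 ± 0.17 SE, adjusted p = 0.0211), Etfa (0.81), Acadm (0.74) and Acadl (0.62).

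Many calls of single members were lost when 1 library was left out, a fit with less power. None of the 7 TCA cycle or 5 fatty acid oxidation calls stayed without PBS 1, PBS 2, Rb2 1 or Rb2 3. Without PBS 4, and likewise without Rb2 4, all 7 and 4 of the 5 stayed. Of the 8 branched-chain calls 2 stayed without PBS 1, 1 without PBS 2, 4 without Rb2 1 and 4 without Rb2 3. Ppm1k was the 1 called in all 6 tests. The offset for GC content and length left 2 of the 7, 2 of the 5 and 6 of the 8 calls, and the muscle covariate 1, 2 and 4. The medians with the offset were 0.48, 0.42 and 0.47, against 0.60, 0.39 and 0.50 without it. Peroxisomal genes (4 higher, 1 lower of 22; 6 and 2 adjusted over the list alone; median 0.27, camera adjusted p = 0.0367, adjusted p = 0.594 with an estimated correlation) included Slc27a2, a very long-chain acyl-CoA synthetase, which rose from 62.7 ± 8.62 to 253 ± 40.8 CPM (2.01 ± 0.17 SE, adjusted p = 0.00166) and kept its call whichever library was left out. Phyh (0.91) and Pex2 (0.64) rose and Pex16 (-0.79) fell. Of its 5 member calls 2 stayed without PBS 1, 1 without PBS 2, 3 without Rb2 1 and 2 without Rb2 3. This list's camera call was lost without Rb2 1 (adjusted p = 0.0732) and without Rb2 3 (adjusted p = 0.119).

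Enzymes of cholesterol synthesis were mostly lower after Rb2: 7 of 22 members fell and 1 rose (13 and 1 adjusted over the list alone; median -0.49, camera adjusted p = 1.24e-05, adjusted p = 0.594 with an estimated correlation). Fdps fell from 68.7 ± 3.30 to 26.3 ± 3.99 CPM (-1.38 ± 0.14 SE, adjusted p = 0.00252), Pmvk from 110 ± 8.45 to 45.4 ± 7.34 CPM (-1.27 ± 0.15 SE, adjusted p = 0.00359). Mvd, which works between them in the mevalonate pathway, fell as well (-1.48 ± 0.26 SE, adjusted p = 0.0125). Fdft1, squalene synthase, was the member that rose (1.17 ± 0.18 SE, adjusted p = 0.00897). It overlaps the much more abundant Ctsb by 774 bases. Fdps and Pmvk were called in all 6 tests with a library left out, and 2 of the 8 calls stayed without PBS 1, 4 without PBS 2, 3 without Rb2 1 and 4 without Rb2 3.

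In de novo lipogenesis 3 of 17 members fell (5 adjusted over the list alone; median -0.53, camera adjusted p = 0.00127, adjusted p = 0.594 with an estimated correlation): the desaturases Fads2 (-1.03 ± 0.15 SE, adjusted p = 0.00727), Fads1 (-0.86) and Scd2 (264 to 132 CPM). Thrsp was at -0.61 (adjusted p = 0.0567, and 0.0480 without Rb2 3). The list's camera call was lost without Rb2 4 (adjusted p = 0.0547), and 1 of the 3 member calls stayed without PBS 1, PBS 2 or Rb2 1. Triglyceride synthesis did not pass camera (3 higher, 1 lower of 14; 4 and 1 adjusted over the list alone; adjusted p = 0.263). Agpat2, an acyltransferase, fell from 1318 ± 106 to 665 ± 86.1 CPM (-0.99 ± 0.16 SE, adjusted p = 0.00984) in all 6 tests with a library left out, while Gk, Agmo (0.72) and Lpin1 (0.65) rose. Of its 4 calls 2 stayed without PBS 1, 1 without PBS 2, 2 without PBS 4, 2 without Rb2 1 and 2 without Rb2 3.

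Transcripts of extracellular matrix, vessels and stroma were lower after Rb2 by camera with the preset correlation. None of these 4 lists passed with an estimated correlation (adjusted p = 0.594 for each). In the extracellular matrix list 17 of 32 members fell and none rose (26 lower and 1 higher adjusted over the list alone; median -0.64, camera adjusted p = 1.06e-09), among them Fbn1, fibrillin, from 21.3 ± 1.88 to 10.1 ± 2.49 CPM (-1.08 ± 0.19 SE, adjusted p = 0.0118), Mmp14 (-1.01), Col5a3 (-0.82) and Col6a1 (-0.74). Of the endothelial markers 10 of 21 fell (14 adjusted over the list alone; median -0.77, camera adjusted p = 2.55e-08), with Cldn5, a tight junction protein, from 87.6 ± 9.37 to 21.1 ± 5.63 CPM (-2.05 ± 0.20 SE, adjusted p = 0.00258), Eng (-1.18), Robo4 (-0.88) and Sox17 (-0.82). Smooth muscle and pericyte markers had 4 of 18 members lower (5 adjusted over the list alone; median -0.71, camera adjusted p = 0.000106): Smtn (39 to 19.5 CPM), Kcnj8 (-1.03), Mcam (-0.99) and Higd1b (-0.96). Adipocyte progenitor and fibroblast markers had 5 of 21 lower and 1 higher (13 and 1 adjusted over the list alone; median -0.77, camera adjusted p = 0.000239), with Thy1 (-0.93) and Gsn (-0.80) among the falls and F3, tissue factor, as the rise (1.33 ± 0.17 SE, adjusted p = 0.00537).

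Without PBS 1, 1 of the 17 matrix calls, 4 of the 10 endothelial calls, 1 of the 4 smooth muscle calls and 1 of the 6 progenitor calls stayed, and without PBS 2 the numbers were 2, 2, 1 and 2. They were 2, 5, 2 and 1 without Rb2 1 and 2, 5, 3 and 2 without Rb2 3. Cldn5, Eng, F3 and Col5a3 kept their calls in all 6 tests. The GC and length offset left 7 of the 17 matrix calls, 8 of the 10 endothelial, 4 of the 4 smooth muscle and 4 of the 6 progenitor calls. The muscle covariate left 6, 8, 4 and 3 of them. With the offset Col5a3 (-0.52, adjusted p = 0.117) and Gsn (-0.62, adjusted p = 0.0974) were among those that lost theirs.

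Of the immune and blood cell lists 4 were lower by camera with the preset correlation. None of these 4 passed with an estimated correlation (adjusted p = 0.594 for each). Of the genes of antigen presentation on MHC class II 4 of 9 fell (5 adjusted over the list alone; median -0.75, camera adjusted p = 0.00017): Cd74 from 134 ± 26.9 to 66.2 ± 6.99 CPM (-1.02 ± 0.17 SE, adjusted p = 0.0101), H2-Ab1 (-1.03), H2-Eb1 (-0.89) and H2-Aa (-0.75). Of these, Cd74, H2-Ab1 and H2-Eb1 were called in all 6 tests with a library left out, and H2-Aa was not (adjusted p up to 0.0809, without Rb2 1). Macrophage markers had 7 of 23 members lower (7 adjusted over the list alone; median -0.42, camera adjusted p = 0.000241), with C1qc (-0.86 ± 0.13 SE, adjusted p = 0.00903), C1qb (-0.79), C1qa (-0.69) and Folr2 (-1.39). Of these 7 calls 1, that of C1qc, stayed without PBS 1, PBS 2, Rb2 1 or Rb2 3. Of the 7, 2 stayed with the GC and length offset and 1 with the muscle covariate.

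Erythroid genes had 4 of 10 members lower (6 lower and 1 higher adjusted over the list alone; median -0.95, camera adjusted p = 0.0127), the haemoglobin genes Hba-a1 (-1.07), Hba-a2 (-1.19), Hbb-bt (-1.15) and Hbb-bs (-1.01), whose near-identical copies make the split between them uncertain. None of these calls stayed without PBS 2, Rb2 1 or Rb2 3 and 1 stayed without PBS 1; with the GC and length offset only that of Hba-a1 stayed. B and plasma cell markers passed camera (median -0.79, adjusted p = 0.0414) with none of 13 members past edgeR's threshold and none adjusted over the list alone. Cd79b was at -1.04 (adjusted p = 0.0841), Fcmr at -1.06 and Ighm at -1.27. That call was lost without PBS 4 (adjusted p = 0.131), without Rb2 1 (adjusted p = 0.133) and without Rb2 3 (adjusted p = 0.129).

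Skeletal muscle markers had lower means after Rb2 in 30 of 30 members, with a median log2 fold change of -3.69, and none passed edgeR's threshold over all genes or adjusted over the list alone (camera adjusted p = 0.0181; adjusted p = 0.755 with an estimated correlation). Tnnc1 (-3.94 ± 1.65 SE, adjusted p = 0.202), Tnni1 (-5.39 ± 2.41 SE), Tnnt1 (-4.60 ± 2.13 SE) and Myl1 (-2.11 ± 0.90 SE; adjusted p = 0.0239 without PBS 4), all contractile proteins, had fold changes that rested on the high levels in PBS 1 and PBS 2. The camera call was lost without PBS 1 (adjusted p = 0.0958), without PBS 2 (adjusted p = 0.24), without Rb2 1 (adjusted p = 0.383) and without Rb2 4 (adjusted p = 0.0503). With the muscle covariate it was lost too (camera adjusted p = 0.697). That covariate is the mean of these same markers, so this loss follows largely from the adjustment itself.

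Immediate early genes and genes of the unfolded protein response passed camera with the preset correlation and not with an estimated correlation (adjusted p = 0.594 for both lists). Immediate early genes had 4 of 22 members lower and 1 higher (5 and 1 adjusted over the list alone; median -0.37, camera adjusted p = 0.0414): Jund fell from 64.6 ± 11.5 to 23.0 ± 1.81 CPM (-1.49 ± 0.15 SE, adjusted p = 0.00258), Fosb (-3.38) and Maff (-1.93) fell, and Myc rose (1.83 ± 0.31 SE, adjusted p = 0.0113). Jund and Fosb were called in all 6 tests with a library left out, while 3 of the 5 member calls stayed without PBS 1, PBS 2 or Rb2 3. The camera call was lost without PBS 2 (adjusted p = 0.0797), without Rb2 3 (adjusted p = 0.154), without Rb2 4 (adjusted p = 0.0556) and with the GC and length offset (adjusted p = 0.0859). Genes of the unfolded protein response were higher (2 of 21, 2 adjusted over the list alone; median 0.28, camera adjusted p = 0.00345), namely Hyou1 (0.64) and Herpud1 (0.69), with Hsp90b1 at 0.51 (adjusted p = 0.0614) and Pdia3 at 0.46 (adjusted p = 0.0807). Neither call stayed without PBS 1, PBS 2, Rb2 1 or Rb2 3, and 1 stayed without PBS 4. Both stayed with the GC and length offset and neither with the muscle covariate.

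Insulin signalling passed camera narrowly (2 of 21 higher, 2 adjusted over the list alone; median 0.34, adjusted p = 0.0492; adjusted p = 0.599 with an estimated correlation), with Insr, the insulin receptor (0.70 ± 0.15 SE, adjusted p = 0.0248), and Sesn1 (0.58) higher, Tbc1d4 at 0.43 and Mtor at 0.48 (adjusted p = 0.0239 without Rb2 4). It lost that call without PBS 1 (adjusted p = 0.0564), PBS 4 (adjusted p = 0.083) or Rb2 1 (adjusted p = 0.383), with the size factors of DESeq2 (adjusted p = 0.0506) and with the muscle covariate (adjusted p = 0.0742). Neither member call stayed without any one of PBS 1, PBS 2, PBS 4, Rb2 1 and Rb2 3. Mitochondrial dynamics, mitophagy and autophagy had 3 of 27 members higher and 2 lower (6 and 3 adjusted over the list alone; median 0.23, camera adjusted p = 0.0335, adjusted p = 0.594 with an estimated correlation). Gabarapl1 (0.79), Bnip3 (0.93) and Opa1 (0.93) rose and Fis1 (-0.61) fell. The camera call was lost without Rb2 3 (adjusted p = 0.129) and with the GC and length offset (adjusted p = 0.0847). Of the 5 member calls 1 stayed without PBS 1, none without PBS 2, 3 without PBS 4, 3 without Rb2 1 and 2 without Rb2 3. Cytosolic ribosomal proteins shifted down by a small amount (1 of 37 lower, none adjusted over the list alone; median -0.25, camera adjusted p = 0.000226, adjusted p = 0.74 with an estimated correlation). Rplp1 (-0.79, adjusted p = 0.0465) was the member called, not so without PBS 1, PBS 2, PBS 4, Rb2 1 or Rb2 3, and Rps19 (-0.68), Rps29 (-0.64) and Rpl13 (-0.59) were not called. These 3 passed without Rb2 4 (adjusted p = 0.0410, 0.0303 and 0.0472).

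Camera thus passed 21 of 43 lists, 8 upward and 13 downward, with the preset correlation, and 0 with an estimated correlation, where 1 list had an unadjusted p under 0.05. The directional test of fry passed 0 (16 with an unadjusted p under 0.05), and its mixed test, which asks whether members change in either direction, passed 31. When the same 6 libraries were split in other ways, 3 against 3, camera with the preset correlation passed 8 to 23 lists, so the number of lists that passed was not larger than that of every other split.

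**Figure D3:**
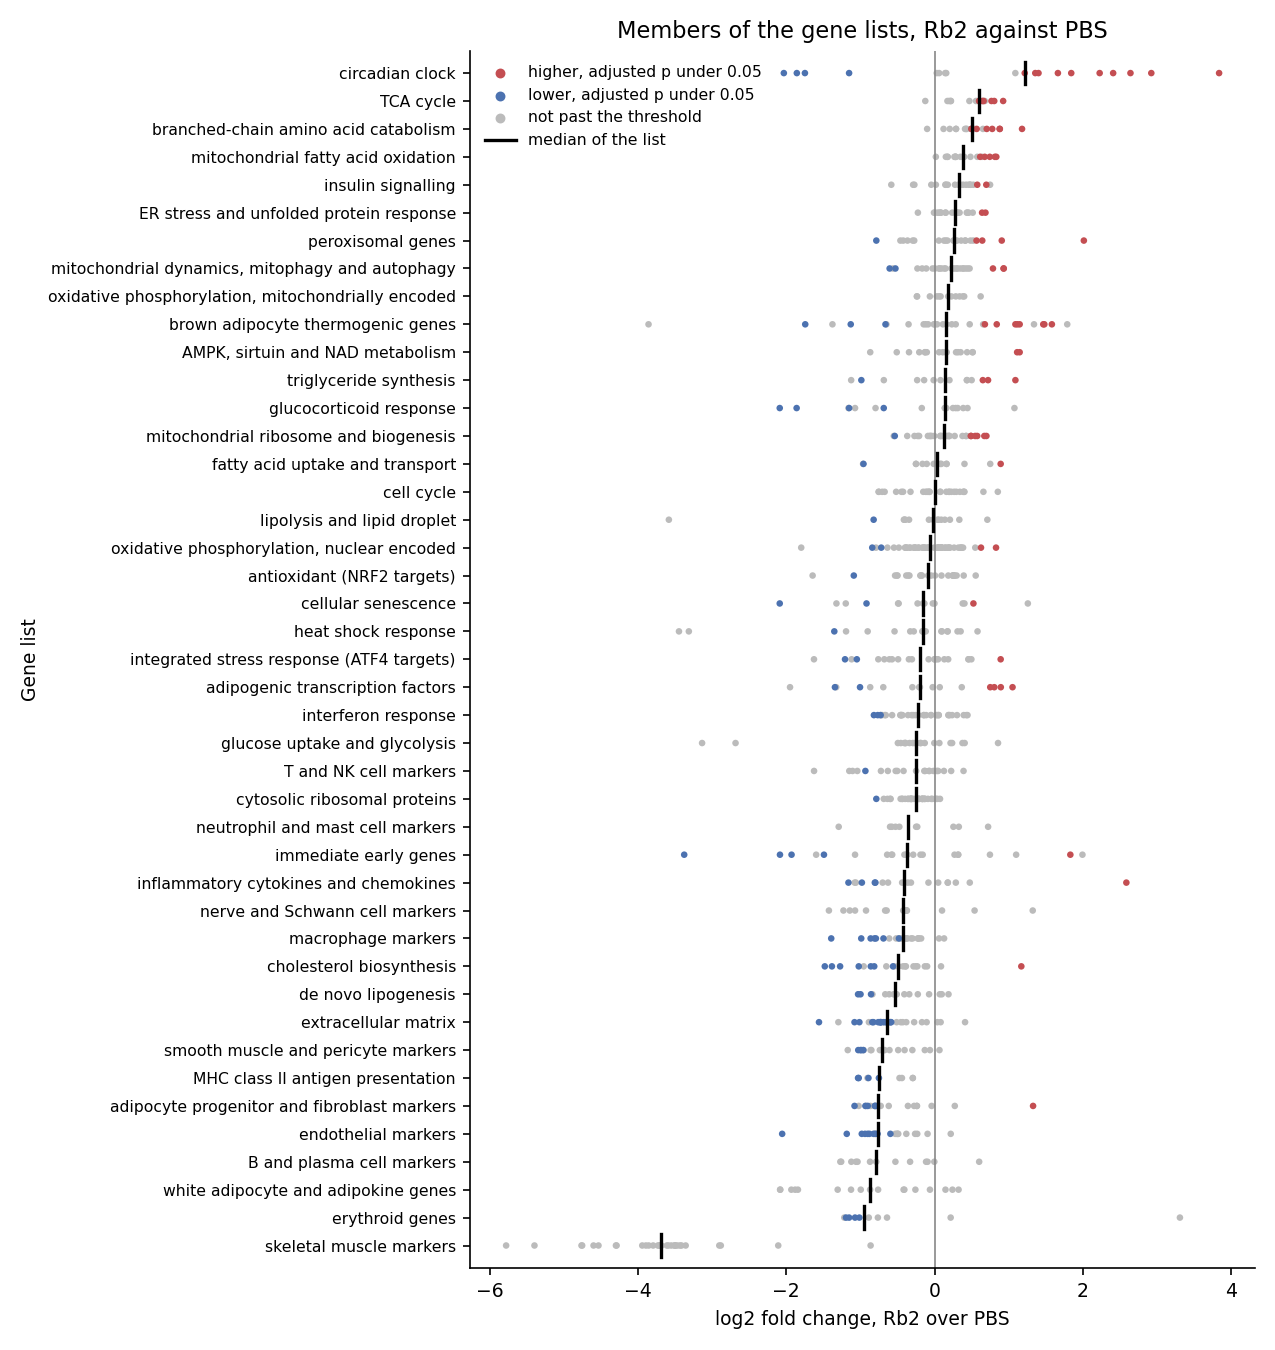
Log2 fold changes (Rb2 over PBS) of the tested members of the 43 lists, 1 point per gene, with the list's median as a black line and the lists ordered by median. Red and blue points passed an adjusted p under 0.05 upward and downward, as did 10 and 4 of the 19 clock genes and 0 and 17 of the 32 extracellular matrix genes; grey points did not pass.

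Lists that did not pass camera held single changes. Adipogenic transcription factors had 4 of 16 members higher and 2 lower (4 and 4 adjusted over the list alone): Stat5a (0.81) and Klf15 (1.05) rose and Gata2 (25.3 to 12.6 CPM) and Cebpb (-1.34) fell. Mitochondrial ribosome and biogenesis genes had 6 of 28 higher and 1 lower (6 and 2 adjusted over the list alone), with Tfb2m (0.67), Gabpa (0.55), Twnk (0.70) and Tfam (0.49) higher. Targets of ATF4 had 1 of 22 higher and 2 lower (3 and 3 adjusted over the list alone). Atf4 itself fell from 142 ± 19.8 to 68.5 ± 12.2 CPM (-1.05 ± 0.17 SE, adjusted p = 0.0102), as did the amino acid transporter subunit Slc3a2 (-1.21), while Vldlr rose (0.89). Ddit4 was at -1.63 (adjusted p = 0.0542). It passed in several other settings, among them without Rb2 1 (adjusted p = 0.0328), the muscle covariate (0.00258), limma-voom (0.0422) and library size alone (0.0455). Glucocorticoid-responsive genes had 4 of 17 lower (1 higher and 4 lower adjusted over the list alone), with Tsc22d3 (-0.68), Cdkn1a (-2.09), Sgk1 (-1.86) and Per1; the list's median of 0.14 and its mean of -0.34 differ in sign. Inflammatory cytokines and chemokines had 4 of 19 lower and 1 higher (5 and 1 adjusted over the list alone), with Cxcl12 (-0.98), Cxcl16 (-1.16) and Tgfb1 (-0.80) lower and Il1rn higher. Interferon response genes had 3 of 35 lower (3 adjusted over the list alone), Irf7 (-0.77), Psmb8 (-0.82) and Psmb9 (-0.73), and Bst2 was at -0.66 (adjusted p = 0.0697). Senescence genes had 1 of 15 higher and 2 lower (2 and 4 adjusted over the list alone), with Cdkn1b (0.52) higher, Igfbp7 (-0.92) and Cdkn1a lower, and Mmp3 at -1.32 (adjusted p = 0.0571, and 0.0274 without Rb2 4).

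Many calls of these 7 lists were also lost when 1 library was left out. Without PBS 1, 1 of the 6 calls among adipogenic factors, 0 of the 7 among mitochondrial ribosome genes and 1 of the 3 among ATF4 targets (Slc3a2) stayed. The numbers without PBS 2 were 1, 0 and 2, without Rb2 1 they were 2, 0 and 2, and without Rb2 3 they were 3, 0 and 2; without PBS 4, 4 of the 7 ribosome calls and 2 of the 3 ATF4 calls stayed. Among glucocorticoid-responsive, interferon, inflammatory and senescence genes 0, 0, 1 (Il1rn) and 0 calls stayed without PBS 1, and 0, 0, 1 and 0 without PBS 2. With the GC and length offset 1 of the 7 mitochondrial ribosome calls (Twnk, while Tfb2m, Gabpa and Tfam lost theirs), 2 of the 4 glucocorticoid, 1 of the 3 interferon and 0 of the 3 senescence calls stayed. With the muscle covariate these numbers were 1 (Tfb2m), 3, 1 and 1 (Igfbp7). Of the adipogenic, ATF4 and inflammatory calls 4 of 6, 3 of 3 and 4 of 5 stayed with the offset, and 3, 2 and 3 with the covariate. Cebpb lost its call with the offset (adjusted p = 0.0566), and Klf15 (adjusted p = 0.0767), Vldlr (adjusted p = 0.0629) and Tgfb1 (adjusted p = 0.0606) lost theirs with the covariate. Without Rb2 1 the numbers for the last 4 lists were 4, 0, 3 and 1, without Rb2 3 they were 1, 0, 2 and 0, and without PBS 4, 2 of the 3 senescence calls stayed.

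Genes of AMPK, sirtuin and NAD metabolism had 2 of 19 higher (5 adjusted over the list alone), Nampt (1.11) and Prkag2 (1.15). Fatty acid uptake genes had 1 of 14 higher and 1 lower (1 and 1 adjusted over the list alone), Vldlr and Gpihbp1 (-0.96). Lipolysis and lipid droplet genes had 1 of 15 lower (1 adjusted over the list alone), Plin2 (-0.82), with Bscl2 at -0.39. Heat shock genes had 1 of 19 lower (1 adjusted over the list alone), Bag3 (-1.35), with Hspd1 at 0.58 (adjusted p = 0.0301 without Rb2 4). NRF2 targets had 1 of 25 lower (1 adjusted over the list alone), Nqo1 (-1.09), with Gpx3 at 0.55 (adjusted p = 0.0204 with the GC and length offset). T and NK cell markers had 1 of 21 lower (1 adjusted over the list alone), Thy1, with Ncr1 at -1.62. The calls of Nampt, Prkag2, Vldlr, Gpihbp1, Plin2, Nqo1 and Thy1 were lost without PBS 1 and without PBS 2, and Bag3 lost its call without Rb2 1 alone. Without Rb2 1, 1 of the 2 calls of the NAD list stayed and none of those of the uptake, lipolysis, NRF2 or T cell lists; without Rb2 3, the uptake and T cell lists kept none; without PBS 4, the lipolysis list kept none and the uptake list 1. No member passed edgeR's threshold, over all genes or adjusted over the list alone, among 22 genes of glucose uptake and glycolysis (Slc2a1 -0.49, Slc16a3 -2.68), 17 white adipocyte genes (Rbp4 -0.87, Wfdc21 -1.84), 10 neutrophil and mast cell markers (Mmp9 -1.29, Kit 0.72), 15 nerve markers (S100b 0.54, Cnp -0.65) and 28 cell cycle genes (Mcm3 -0.71, Rrm2 0.85). Of the genes in brackets Slc2a1 passed without Rb2 4 (adjusted p = 0.0321), and Slc16a3 (adjusted p = 0.0295), Wfdc21 (adjusted p = 0.0434) and S100b (adjusted p = 0.0149) without PBS 4. Rbp4 passed with library size alone (adjusted p = 0.0301) and with a count minimum of 50 (adjusted p = 0.0399). The DESeq2 Wald test passed Rbp4, Wfdc21, Slc16a3, Mmp9, Mcm3 and Kit (adjusted p = 0.00158, 0.0116, 0.0286, 0.0306, 0.0329 and 0.0365). Slc16a3 was highest in the muscle-rich PBS 2 (6.16 CPM), and its log2 fold change was -1.54 without that library and -1.40 with the muscle covariate. No member passed edgeR's threshold among 3 markers of other tissues either, a list too short for camera (Cd1d1 0.24, Cdh1 -1.78). The camera adjusted p of the lists named in these paragraphs on lists that did not pass ran from 0.0767 to 0.992. For fatty acid uptake (median 0.0330, mean -0.0117) and the cell cycle (median 0.00289, mean -0.0237) the median differed in sign from the mean and from the direction of the test.

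Some of these lists passed camera with the preset correlation in other settings. Without PBS 4 the white adipocyte (adjusted p = 0.000562), interferon (adjusted p = 0.00466), mitochondrial ribosome (adjusted p = 0.00848), inflammatory (adjusted p = 0.0376) and T and NK cell lists (adjusted p = 0.0394) passed. Without PBS 2 the heat shock (adjusted p = 0.00359) and white adipocyte lists (adjusted p = 0.0286) passed. Without Rb2 1 the mitochondrial ribosome (adjusted p = 0.0165) and glucocorticoid lists (adjusted p = 0.0279) passed. Without Rb2 3 the heat shock (adjusted p = 0.00118) and glycolysis lists (adjusted p = 0.00653) passed, and without Rb2 4 the inflammatory list (adjusted p = 0.0284). With the GC and length offset the interferon (adjusted p = 0.0365) and inflammatory lists (adjusted p = 0.0404) passed, and without a filter the mitochondrial ribosome list (adjusted p = 0.0484). The mitochondrial ribosome list was higher and the others lower.

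Over the 126 named genes that passed the threshold, 43 did so without PBS 1, 43 without PBS 2, 65 without Rb2 1, 66 without Rb2 3, 108 without PBS 4 and 121 without Rb2 4, and 32 did so in all 6 of these tests. With the GC and length offset 91 of the 126 stayed and with the muscle covariate 89. Among those that lost the call with the offset were Pex16 (adjusted p = 0.0908), Agmo (adjusted p = 0.0546), Plin2 (adjusted p = 0.0754), Fis1 (adjusted p = 0.0712) and Rplp1 (adjusted p = 0.136). The covariate ended the calls of Agmo (adjusted p = 0.0561), Plin2 (adjusted p = 0.0799), Fis1 (adjusted p = 0.0776) and Rplp1 (adjusted p = 0.0756) too, and those of Lpin1 (adjusted p = 0.117), Insr (adjusted p = 0.0640) and Prkag2 (adjusted p = 0.0522).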

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

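The tests chosen only after the data were seen were the replicate block, the muscle covariate, the GC and length offset, and leaving out both PBS 1 and PBS 2. DESeq2's size factors, upper-quartile factors, limma-voom, no filter and a count minimum of 50 gave 1583 to 2163 genes. Leaving out 1 library gave 303 (without PBS 2) to 2269 (without Rb2 4) genes, 121 (without PBS 1) to 1200 (without Rb2 4) higher and 181 (without PBS 2) to 1069 (without Rb2 4) lower. With library size alone 492 were higher. The DESeq2 Wald test called 3153 genes (1595 higher, 1558 lower), the threshold of 0.1, a looser one, 3392 (1757 and 1635), and the 2-fold minimum, a stricter one, 564 (242 and 322). The muscle covariate left 893 (421 and 472). For settings without a stated reason the cause was not tested.

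The replicate block on the column numbers that both groups carry called 96 genes (42 higher, 54 lower) and 21 lists. Of these genes 60 were called in the same direction among the 1743 of the main fit. The numbers of PBS 2 and Rb2 3 occur in 1 group only, so these libraries added nothing to the comparison. It rested on PBS 1, PBS 4, Rb2 1 and Rb2 4 with few residual degrees of freedom, so the drop in calls cannot be read as an effect of pairing. The block also assumes a pairing that the labels do not give. Deviations of same-numbered libraries from their group means had an r across genes of -0.197 for number 1 and -0.215 for number 4. A block on the titles' numbers was planned and not run, since no column can be tied to them. With PBS 1 and PBS 2 left out edgeR called 0 genes (0 higher, 0 lower; 2063 with an unadjusted p under 0.05). That leaves 1 PBS library, which is assumed to vary like the others.

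Of the lists, 0 passed camera with an estimated correlation (1 with an unadjusted p under 0.05) and 0 passed the directional test of fry (16 unadjusted). The other list tests passed 19 to 31. Over the named genes' alternatives 2365 values kept direction and side of the threshold, 714 no longer passed it, 73 newly passed it and 14 reversed. For the 21 lists that passed camera, over the alternatives other than the estimated correlation and fry, 225 values stayed the same in this sense, 25 no longer passed and 2 reversed. Of the lists that did not pass, the brown adipocyte list (adjusted p = 0.0383), interferon response (adjusted p = 0.0365) and inflammatory list (adjusted p = 0.0404) newly passed with the offset, and others newly passed without single libraries, such as the white adipocyte list without PBS 4 (adjusted p = 0.000562) and heat shock genes without PBS 2 (adjusted p = 0.00359). With the offset the median also changed sign for adipogenic factors (-0.202 to 0.00405), nuclear oxidative phosphorylation (-0.0595 to 0.0282), lipolysis (-0.0171 to 0.0612), fatty acid uptake (0.0330 to -0.0528), cell cycle genes (0.00289 to -0.131) and markers of other tissues (0.166 to -0.0531).

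Other reversals were found for values near 0, for muscle markers and for Cdh1 and S100b. With 1 library left out, the log2 fold change of Ucp1 ran from -0.33 (without Rb2 3) to 0.0254 (without Rb2 1), that of Ppargc1a from -0.16 (without PBS 4) to 0.19 (without PBS 2), and that of Cidea from -0.00374 (without Rb2 4) to 0.27 (without Rb2 1). Ppargc1a was at -0.0567 with library size alone and at -0.19 with the offset. With PBS 1 and PBS 2 left out Tnnc1 was at 0.54, Myl1 at 0.19, Tnni1 at 1.80, Tnnt1 at 1.57, Cdh1 at 1.11 and S100b at -0.00634. The skeletal muscle list's median was 4.41 there and 0.28 with the muscle covariate, where Cdh1 was at 0.0153. These settings take out the libraries or the score that carry most of the muscle signal. A 2-fold change was recovered in 40 of 100 simulated genes, so changes of that size can be missed. In that simulation 124 genes were called, against 1743 in the real fit, and the adjusted threshold depends on how many genes change. The 40 of 100 therefore does not measure the share of 2-fold changes found in the real comparison. Smaller changes were not simulated.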

Other observations

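All tests in this part were chosen only after the result was seen, except the counts of other splits of the libraries.

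The clock genes changed together. With the GC and length offset 13 of the 14 called clock genes stayed past the threshold and with the muscle covariate 14 did, which argues against either as the whole cause. All 13 called genes of the limbs led by Arntl and by Dbp moved in opposite directions, 3 lower and 10 higher. The remaining called gene, Per1 (-1.15), fell as its relatives Per2 and Per3 rose and was placed in neither limb. The limbs were drawn up after the directions were seen, so the count of 13 describes the pattern and does not test it. A later or earlier time of collection in 1 group and a shift of the clock by Rb2 both predict limbs that move in opposite directions. The labels give no collection time, so for these genes they cannot be told apart. A difference in collection time would apply to the whole comparison. Which other called genes vary with the time of day was not tested, so this limit may reach beyond the clock genes.

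Lists of matrix, endothelial, progenitor, smooth muscle, macrophage and MHC class II genes were lower and those of the TCA cycle, fatty acid oxidation and branched-chain amino acids higher. Of these 9 lists, picked after it was seen that they passed, 9 passed camera with the GC and length offset and 9 with the muscle covariate, while the offset moved the matrix median from -0.64 to -0.52 and left 7 of its 17 member calls, and the covariate 6. This counts only weakly against either as the whole cause, since none of the 9 passed with an estimated correlation (adjusted p = 0.594 for each) and another split of the libraries passed 23 lists. Endothelial markers differed by unequal amounts (Cochran's Q over its 20 degrees of freedom 5.23, limit 1.57, and 3.72 with the offset). They ran from 0.22 ± 0.47 SE for Prox1, which is at 0.215 CPM with PBS, and -0.09 for Erg to -2.05 for Cldn5. Q takes the markers as independent and their SEs as known. Markers that other cells also make would fall less, so unequal falls cannot decide whether a smaller share of endothelial cells alone accounts for them. Cdh5 went from 373, 402 and 406 CPM in PBS 1, 2 and 4 to 208, 202 and 271 CPM in Rb2 1, 3 and 4, 20 of the 21 markers had at least 1 CPM in every library and 0 are in another list, and a change in the make-up of the depot stays open beside an effect of Rb2 on its cells.

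Skeletal muscle markers were lower in Rb2 on average. Their log2 CPM rose and fell together over the 6 libraries (median pairwise Pearson r 0.961), and 30 of 30 were highest in PBS 2, so muscle dissected along with the fat is a candidate explanation. Acta1 was at 375, 1612 and 1.24 CPM in PBS 1, 2 and 4 and at 0.118, 66.3 and 34.8 CPM in Rb2 1, 3 and 4. Of the 30 markers 0 were lower in every Rb2 library than in every PBS library. As the markers vary together, this is not 30 separate results. The muscle share of the counts was 0.0155% in PBS 4, below that in Rb2 3 (0.0675%) and Rb2 4 (0.0503%). With such a spread within PBS the count cannot decide whether Rb2 also acted on these transcripts. In every library 5 of the 30 had at least 1 CPM, and 1, Des, is in another list.

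The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The real split called 1743 genes and the highest other 1, so 1 of the 10 gave as many. It passed 21 lists and the highest other 23, so 2 of the 10 passed as many.

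Families and genes noticed in the data were looked at further, with Fisher's exact test (two-sided, 6 tests). The families were noticed in these same calls and the exact test takes genes as independent, so its p-values do not measure replication over mice. Of 371 tested genes with a Zfp symbol 53 were higher and 5 lower (exact test for the higher ones, adjusted p = 2.85e-10). With the GC and length offset 26 and 2 were (exact test for the higher ones, unadjusted p = 0.0196, against 4.75e-11 without the offset). The median GC content of the family was 43.9%, against 49.8% for all genes. Of 24 genes with a Tub symbol, which need not all be tubulins, 7 were lower (exact test, adjusted p = 0.000373). With the offset 3 were, where the unadjusted p of 0.0522 is not past 0.05. Of 252 Slc genes 26 were higher (adjusted p = 0.00231) and 12 lower (adjusted p = 1). With the offset 27 were higher (unadjusted p = 1.64e-05) and 8 lower. Under the other scalings Zfp had 30 to 51 higher, Tub 7 to 8 lower and Slc 16 to 27 higher. Srf, a transcription factor of actin genes (-1.29 ± 0.14 SE), Zyx (-1.48), Vasp (-1.19), Fblim1 (-1.39), Vcl (-0.91), Filip1l (-0.83), Tubb2a (-1.60) and Tubb2b (-1.60) were lower, with calls that stayed whichever library was left out.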
